A study of Homo sapiens with 8 samples.

How the data were processed

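The series holds 8 RNA-seq libraries of HEK293T cells, 4 of untreated cells and 4 of cells given 20 mM 2-DG, grouped by the treatment label of each sample. Per the labels' protocols, total RNA was extracted with a TransZol Up kit and libraries were made with an NEBNext Ultra RNA kit. Poly(A) selection, strand setting, read length and treatment time are not given in the sources used here, so reads of a gene and of an antisense or overlapping neighbour cannot be told apart. Per the submitters' processing notes, the tools were FastQC 0.11.9, HISAT2 2.2.1, featureCounts 2.0.3 and edgeR 3.40.2 with the build hg38. Their roles, options and annotation release are not given in the sources used here.

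The authors deposited 1 table, with a row per expressed gene and FPKM values (fragments counted per kilobase of gene, scaled to library size) for each library. The deposited table also holds the authors' log2 fold change of 2-DG over control and mean log2 CPM, and their p-value with its adjusted form, per the file headers. It had 14109 rows, 1 of them empty, and so 14108 genes. The authors' rule for an expressed gene is not given in the sources used here. No FPKM value was 0, and the lowest was 0.00502. Of the gene identifiers, 13128 were current symbols and 749 older ones, matched through the GENCODE release 29 annotation (GRCh38) and gene name tables. A further 21 identifiers were dates, as a spreadsheet makes of symbols such as those of septins and MARCH genes, 4 of them repeated, and they were kept under their own names. The 13 mitochondrially encoded mRNAs of a planned list were not among the rows, so their share was not analysed here. Coordinates are those of GENCODE release 29 on GRCh38.

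Depth was recovered from the FPKM values. Within a gene the values of the 8 libraries, times a relative depth per library, were whole-number multiples of 1 unit, within 0.001 reads for 100% of the genes (largest deviation 5.3e-05). On simulated reads, 99.8% of 4962 genes were recovered up to a common factor of their reads, and 0.44% had such a factor, which cannot be seen from FPKM. The reads summed to between 15048004 and 16726189 per library. Replicates of a group differed by 1.17 to 2.52 times the chi-square that counting noise gives at the median gene, so no library's values were a copy of another's, while repeat libraries of the same RNA were not excluded.

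The unit was not a count, so the main test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust) on log2(FPKM + 1), for genes with at least 1 FPKM in at least 4 libraries, with no covariate. Fold changes are on this log2 scale with a pseudocount of 1, which understates changes of low genes. Folds given for single genes are ratios of mean FPKM. Counts made here of genes changed at least 2-fold or under 1.5-fold are on the log2 scale. Adjusted p-values are Benjamini-Hochberg values over the 12591 genes tested, with a threshold of 0.05, and a separate count took genes with a log2 change of at least 1. The 30 gene lists were fixed before the data were examined, with the alternatives and the rule for named genes. The 28 lists with 5 or more tested genes were tested by camera with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. Shares of summed FPKM were compared by an exact permutation test over the 70 assignments of 4 and 4 libraries.

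Genes named by the rule were the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 FPKM in the higher group and groups that did not overlap. Dates and clone or locus names were left out of these, so they are not the largest changes of all genes tested. The rule also took the 3 members of each list with the smallest p, and HAT1, EP300, SIRT3, HK1, HK2, GPI, HSPA5, DDIT3, TXNIP, SLC2A1, LDHA, GAPDH and ACTB. Other list members that went against their list, or that did not pass, were named after their values were seen, and 2 genes that the rule took are not reported here.

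The fit was tested on simulated data, in which 200 of 12513 genes were changed in a comparison of 4 against 4 libraries. Values were drawn around each gene's mean over all 8 libraries. The spread between replicates was a trend smoothed over mean expression, not each gene's own. The fit called 75.5% of the genes changed 1.25-fold, 98.0% of those changed 1.5-fold, 98% of those changed 2-fold and 98% of those changed 3-fold. Of the unchanged genes it called 0.0974%. In the real data 72.9% of the genes tested passed, which loosens the Benjamini-Hochberg cutoff. The rate for unchanged genes therefore does not carry over to the real data. A list made only of simulated raised genes was called, and 0 of 29 unchanged lists were. The simulated genes were drawn independently, whereas the estimated correlation within the real lists reached 0.353, in the cytosolic heat shock list. The list result therefore does not show how camera with the preset correlation behaves on lists whose genes move together.

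The alternatives were the replicate number as a block, leaving out each library, limma without trend and robust, a common median, quantile normalization, no filter or a filter of 5 FPKM, pseudocounts of 0.1 and 0.01, and a threshold of 0.01 for the overlap with the authors' table. Alternatives chosen after the data were seen were limma voom on the recovered reads, removal of each library's trend on counted length and reference GC content (a GC value was found for 97.4% of genes), and leaving out genes whose counted length, implied by reads and FPKM, was at least 1.8 times the reference exon length. Count models on deposited counts were planned for a count table and were not used, since the table holds FPKM. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and statmod 1.5.0.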

Results

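HEK293T cells, a transformed human embryonic kidney line that carries the SV40 large T antigen, were profiled by RNA sequencing as untreated controls (4 libraries) and after exposure to 2-deoxy-D-glucose (2-DG) at 20 mM (4 libraries). 2-DG is a glucose analogue that hexokinase phosphorylates but that glycolysis cannot carry further, and it also interferes with N-linked glycosylation. The comparison asks which transcripts differ between cells with and without the inhibitor, in a study of lysine pyruvylation whose title names HAT1, p300 and SIRT3. The labels give no treatment time and do not say whether the 4 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Each library held between 15048004 and 16726189 reads assigned to the 14108 genes of the deposited table, as recovered from the FPKM values (fragments counted per kilobase of gene, scaled to library size). The first principal component carried 85.6% of the variance and separated the groups, and the second carried 4.4%.

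Among genes at 5 FPKM or more in the higher group, stress genes of the endoplasmic reticulum (ER) had the largest rises on the log2(FPKM + 1) scale, and ETV4 and TIMP1 the largest falls. DDIT3, the stress transcription factor CHOP (chromosome 12, 57516588 to 57521737, GRCh38), rose from 12.9 ± 0.716 to 97.6 ± 3.11 FPKM (SD, n = 4 libraries per group here and below). HERPUD1, a component of ER-associated degradation (chromosome 16, 56932048 to 56944863), rose from 51.4 ± 2.50 to 322 ± 7.91 FPKM, and HSPA5, the ER chaperone BiP (chromosome 9, 125234853 to 125241330), from 306 ± 16.9 to 1367 ± 52.4 FPKM. ETV4, an ETS transcription factor (chromosome 17, 43527844 to 43579620), fell from 32.1 ± 1.29 to 3.71 ± 0.209 FPKM. TIMP1, a secreted inhibitor of matrix metalloproteinases (chromosome X, 47582313 to 47586789), fell from 1229.6 ± 48.0 to 185 ± 2.78 FPKM.

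With the same limit and scale, the 10 largest rises were DDIT3 (2.82), HERPUD1 (2.62), HSPA5 (2.16), DNAJB9 (2.08), PDIA4 (2.04), MANF (1.99), TXNIP (1.94), HYOU1 (1.89), SHC2 (1.84) and INHBE (1.83). The 10 largest falls were ETV4 (-2.81), TIMP1 (-2.73), ITM2A (-2.42), CA2 (-2.34), CITED1 (-2.13), SHISA2 (-2.02), EGR1 (-1.86), FOXCUT (-1.86), ETV5 (-1.85) and DUSP6 (-1.75). The length over which FOXCUT was counted was 6.56 times its reference exon length. The largest limma Benjamini-Hochberg adjusted p among these 20 genes was 1.2e-08, for SHC2. In each of them all 4 libraries of 1 group lay above all 4 of the other, which the rule that picked them required.

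**Figure D1:**
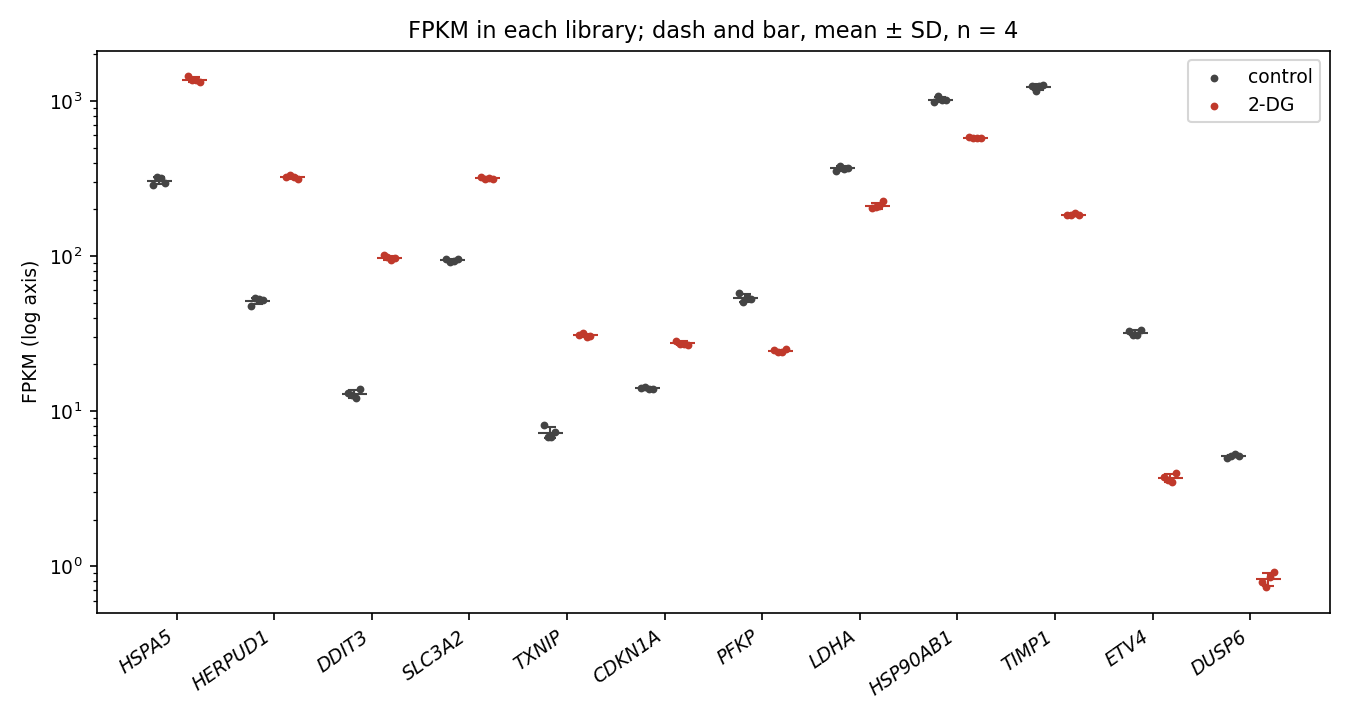
FPKM on a log axis for 12 named genes in each control (grey) and 2-DG (red) library, with points for libraries and a dash and bar for the mean ± SD (n = 4). HSPA5 rose from a mean of 306 to 1367 FPKM and TIMP1 fell from 1229.6 to 185 FPKM, with no overlap between the groups in any of the 12 genes. For those among the largest rises and falls, the rule that picked them required this.

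Of 12591 genes tested, 9183 (72.9%) changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 4543 of them higher and 4640 lower in 2-DG. Counts of higher and lower list members below are to be read against these shares. Most of these changes were small on the log2(FPKM + 1) scale, where 7740 of the 9183 (84.3%) were under 1.5-fold. This share was not counted with a smaller pseudocount. At least 2-fold changes on the log2(FPKM + 1) scale were found for 285 genes, 152 higher and 133 lower. The groups did not overlap in 8318 genes (66.1%), where chance gives 2.86%. That scale understates changes of low genes, and the 2-fold count was 622 with a pseudocount of 0.1, 686 with 0.01 and 679 by limma voom on the recovered reads. Higher genes made up 53.3% of the 2-fold set. They made up 67.5% of the 277 genes that passed after the trends on gene length and GC content were removed, a partly different set.

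**Figure D2:**
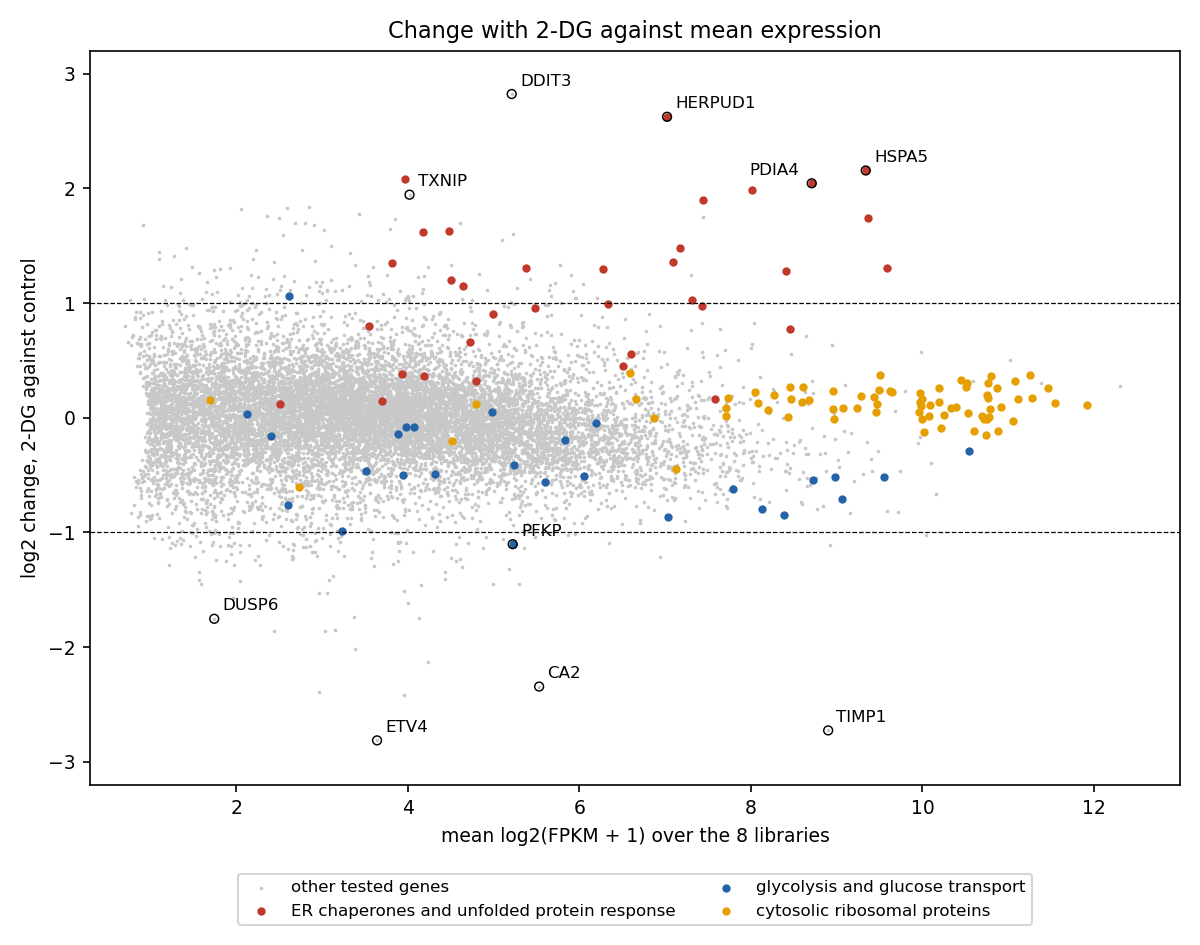
Log2 change in 2-DG against control, of FPKM + 1, plotted against the mean log2(FPKM + 1) over the 8 libraries for the 12591 tested genes; dashed lines mark 2-fold changes. ER chaperone genes (red) lie above 0, most glycolytic genes (blue) lie below 0, and ribosomal protein genes (orange) lie close to 0 at the highest expression.

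All 34 tested genes of the ER chaperone and unfolded protein response list rose in 2-DG (34 adjusted over the list alone), 19 of them at least 2-fold, with a median log2 change of 1.18. PDIA4, an ER protein disulfide isomerase, rose 4.14-fold (205 ± 5.58 to 849 ± 17.6 FPKM), and HYOU1, an ER chaperone of the HSP70 family, rose 3.75-fold (89.4 ± 3.49 to 335 ± 6.40 FPKM). DNAJB9, a BiP cochaperone, rose 4.70-fold and MANF, a secreted ER stress protein, 3.99-fold. The list as a whole stood above the other genes (limma camera, adjusted p = 8.97e-18 with a preset correlation of 0.01; adjusted p = 0.120 with an estimated correlation).

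Genes of the integrated stress response, which the transcription factor ATF4 controls, rose with them: 38 of 42 were higher, 2 lower and 2 did not pass (38 higher and 3 lower adjusted over the list alone). SLC3A2, the heavy chain of amino acid exchangers at the cell surface, rose 3.38-fold (93.6 ± 1.70 to 317 ± 3.82 FPKM), the transcription factor ATF3 2.40-fold and SESN2, a leucine sensor, 2.56-fold. The members that fell were ALDH18A1 and PYCR1, enzymes of proline synthesis. The median log2 change of the list was 0.59 (camera adjusted p = 3.44e-13; adjusted p = 0.120 with an estimated correlation). The cytosolic aminoacyl-tRNA synthetases, many of which are also ATF4 targets, did not rise together. Of 19, 7 were higher, 8 lower and 4 did not pass (7 higher and 8 lower adjusted over the list alone). These shares were close to those of all tested genes, with 4543 higher and 4640 lower of 12591. SARS, WARS and AARS rose by 0.40, 0.52 and 0.32 on the log2 scale. Their list's median was 0.03 (-0.03 after the length and GC trends were removed) and its mean -0.01, and camera did not call it (direction up, adjusted p = 0.912).

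Targets of p53 rose in 22 of 24 genes tested, and 2, PLK3 and TIGAR, did not pass (22 higher adjusted over the list alone). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 1.95-fold (14.1 ± 0.228 to 27.5 ± 0.743 FPKM), and BBC3, the pro-apoptotic BH3 protein PUMA, 2.54-fold (7.77 ± 0.345 to 19.8 ± 1.16 FPKM). The large T antigen of HEK293T cells binds p53, and CDKN1A, GDF15 and SESN2 stand in the ATF4 list as well. The median log2 change was 0.72 (camera adjusted p = 3.86e-10; adjusted p = 0.0541 with an estimated correlation). Of 27 apoptosis regulators, 15 were higher, 9 lower and 3 did not pass (15 and 9 adjusted over the list alone), among them HRK, another BH3 protein, which rose 3.08-fold, and TNFRSF10B, the death receptor DR5, which rose 1.8-fold. The apoptosis list was not called (camera adjusted p = 0.185).

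Glycolytic enzymes fell in 2-DG: 19 of 27 genes for glycolysis and glucose transport were lower, 1 higher and 7 did not pass (19 and 1 adjusted over the list alone). PFKP, a phosphofructokinase, fell from 53.8 ± 3.11 to 24.5 ± 0.456 FPKM, PGAM1, phosphoglycerate mutase, from 176 ± 1.93 to 96.3 ± 4.69 FPKM, and PKM, pyruvate kinase, from 685 ± 6.37 to 419 ± 12.4 FPKM. LDHA, lactate dehydrogenase A, had a log2 change of -0.79, HK1, a hexokinase, of -0.56 and GPI, the glucose phosphate isomerase that 2-DG 6-phosphate inhibits, of -0.51. HK2 had a log2 change of -0.08 (limma adjusted p = 0.0668) and SLC2A1, the glucose transporter GLUT1, of -0.15 (adjusted p = 0.0615), neither past the threshold. Both lay close to it: SLC2A1 passed with the replicate number as a block (adjusted p = 0.0102), and both passed after quantile normalization (0.0258 for HK2 and 0.0296 for SLC2A1) and by voom (0.0395 and 0.0399). The member that rose was ENO3, an enolase known mainly from muscle. The median log2 change of the list was -0.50 (camera adjusted p = 2.19e-06; adjusted p = 0.125 with an estimated correlation).

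Of the pentose phosphate pathway, 7 of 11 genes were lower, 3 higher and 1 did not pass (7 and 3 adjusted over the list alone). PRPS2, PRPS1 and TALDO1 fell by 0.88, 0.61 and 0.62 on the log2 scale, and H6PD, PGD and PGLS rose. The list was not called (camera adjusted p = 0.120). Around the glucose-phosphate sensor MondoA, 5 of 12 genes rose, with TXNIP, an arrestin that limits glucose uptake, 4.23-fold (7.29 ± 0.612 to 30.8 ± 0.803 FPKM), the transcription factor KLF11 2.42-fold and the arrestin ARRDC4 2.19-fold. The others that rose were KLF10 and MLXIP, which encodes MondoA, while ARRDC2 and MLX, the partner of MondoA, fell and 5 did not pass (5 higher and 2 lower adjusted over the list alone). The MondoA list was not called (median log2 change 0.14, camera adjusted p = 0.120).

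Nuclear genes for mitochondrial energy metabolism, with some cytosolic enzymes listed beside them, fell by smaller amounts. Of 67 subunits of oxidative phosphorylation, 61 were lower, 0 higher and 6 did not pass (61 lower adjusted over the list alone), with a median log2 change of -0.30 (-0.18 after quantile normalization and -0.17 after the length and GC trends were removed; camera adjusted p = 1.68e-11; adjusted p = 0.169 with an estimated correlation). The ATP synthase subunit genes ATP5G1 and ATP5G3 and the complex I subunit gene NDUFS5 had log2 changes of -0.78, -0.66 and -0.71. Of 37 pyruvate and TCA cycle genes, 31 were lower, 2 higher and 4 did not pass (31 and 2 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 9.74e-06; adjusted p = 0.125 with an estimated correlation). The mitochondrial malate dehydrogenase MDH2, its cytosolic counterpart MDH1 and the cytosolic ATP citrate lyase ACLY fell by 0.46, 0.43 and 0.33 on the log2 scale. PC, pyruvate carboxylase, and MPC1, a subunit of the mitochondrial pyruvate carrier, rose.

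Cytosolic chaperones went the other way from those of the ER. Of 22 genes of the cytosolic heat shock response, 20 were lower and 2, DNAJB4 and HSF1, higher (20 and 2 adjusted over the list alone), with a median log2 change of -0.63. HSP90AB1, the constitutive HSP90, fell from 1017 ± 36.1 to 578 ± 5.50 FPKM, and its cochaperones STIP1 and AHSA1 had log2 changes of -0.78 and -0.72. Camera placed the list below the other genes (adjusted p = 1.05e-07; adjusted p = 0.195 with an estimated correlation).

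N-glycosylation genes rose more often than they fell, with 27 of 45 higher, 14 lower and 4 not passing (27 and 14 adjusted over the list alone). GFPT1, which makes glucosamine 6-phosphate for the hexosamine pathway, rose 2.48-fold (10.4 ± 0.327 to 25.7 ± 1.27 FPKM), MAGT1, an oligosaccharyltransferase subunit, 2.18-fold and STT3A, a catalytic subunit of that enzyme, 1.75-fold. The median log2 change was 0.20 (0.13 with a filter of 5 FPKM; camera adjusted p = 0.0112; adjusted p = 0.169 with an estimated correlation).

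Ribosomal protein genes were slightly higher, and genes for making ribosomes were lower. Of 75 cytosolic ribosomal protein genes, 48 were higher, 8 lower and 19 did not pass (48 and 8 adjusted over the list alone). Their median log2 change was 0.12 (0.14 after quantile normalization and 0.25 after the length and GC trends were removed; camera adjusted p = 5.81e-05; adjusted p = 0.352 with an estimated correlation), and RPL10, RPLP0 and RPL13A rose by 0.37, 0.37 and 0.31. These genes have processed pseudogenes that can share their reads, as have GAPDH, LDHA and ACTB. Of 44 ribosome biogenesis genes, 33 were lower, 3 higher and 8 did not pass (33 and 3 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 6.08e-06; adjusted p = 0.202 with an estimated correlation). NOP10 and NHP2, of the box H/ACA ribonucleoprotein, and RRP9, of the U3 particle, had log2 changes of -0.62, -0.40 and -0.56, and NOB1, NOP14 and PPAN rose.

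Mitotic genes fell in 31 of 46 cases, 2, BUB3 and FOXM1, were higher and 13 did not pass (31 and 2 adjusted over the list alone). PTTG1, or securin, and the kinase AURKA had log2 changes of -0.87 and -0.76, and CDC20, an activator of the anaphase-promoting complex, of -0.50. The median was -0.26 (camera adjusted p = 9.74e-06; adjusted p = 0.202 with an estimated correlation). DNA replication genes were lower in 27 of 48 cases, higher in 11, and 10 did not pass (27 and 11 adjusted over the list alone). The helicase subunit genes MCM5 and MCM4 had log2 changes of -0.47 and -0.30, while CDC6, which loads that helicase, rose by 0.62. The replication list lay close to the threshold (median -0.14, camera adjusted p = 0.0417; adjusted p = 0.160 with an estimated correlation), and its call was lost without 2-DG replicate 1 (0.0565), 3 (0.0553) or 4 (0.0650) and after quantile normalization (0.344), with a filter of 5 FPKM (0.0791) or after the length and GC trends were removed (0.0955).

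Of the 56 replication-dependent histone genes listed, 12 were in the table, and 9 of these rose, 1, HIST2H2AC, fell and 2 did not pass (9 and 1 adjusted over the list alone). Poly(A) selection is not given, so which histone transcripts the libraries could capture is not known, and these values may not stand for histone expression as a whole. HIST1H2BD rose 2.56-fold, HIST1H1C 1.66-fold and HIST1H2BK 1.43-fold, the last counted over 2.99 times its reference exon length. The median log2 change was 0.59 (camera adjusted p = 0.00737; adjusted p = 0.120 with an estimated correlation).

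Extracellular matrix and adhesion genes fell in 30 of 42 cases, 4 rose and 8 did not pass (30 and 5 adjusted over the list alone). Beside TIMP1, LAMB1, a laminin chain, fell from 27.2 ± 0.748 to 13.6 ± 0.406 FPKM and COL18A1, a basement membrane collagen, from 10.8 ± 0.191 to 5.44 ± 0.262 FPKM. The adhesion molecules L1CAM and NCAM1, the integrin ITGA1 and the lysyl oxidase LOXL1 rose. The median log2 change was -0.31 (-0.57 over the 23 genes left by a filter of 5 FPKM; camera adjusted p = 6.08e-06; adjusted p = 0.0632 with an estimated correlation).

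Immediate early genes were lower in 15 of 24 cases, 7 were higher and 2, IER5 and MYC, did not pass (15 and 7 adjusted over the list alone). EGR1, an early growth response transcription factor, fell from 14.7 ± 1.75 to 3.30 ± 0.162 FPKM, DUSP6, an ERK phosphatase, from 5.15 ± 0.0976 to 0.825 ± 0.0772 FPKM, and SPRY4, a feedback inhibitor of receptor signalling, from 3.84 ± 0.159 to 0.812 ± 0.0257 FPKM. The list as a whole was not called (camera adjusted p = 0.106).

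The enzymes of the study's title changed by less than 1.5-fold. HAT1, a histone acetyltransferase, fell from 77.0 ± 5.35 to 63.0 ± 3.94 FPKM (log2 change -0.28 ± 0.053 SE, limma adjusted p = 0.000415), SIRT3, the mitochondrial deacetylase, from 9.52 ± 0.257 to 8.16 ± 0.702 FPKM (-0.20 ± 0.052, adjusted p = 0.00414), and EP300, which encodes p300, rose from 19.1 ± 0.871 to 23.9 ± 0.335 FPKM (0.31 ± 0.036, adjusted p = 8.9e-06). Of 36 genes listed as writers and erasers of lysine acylation, 17 were higher, 13 lower and 6 did not pass (17 and 13 adjusted over the list alone). The list also held genes that do neither, such as ACLY, RBBP4 and RBBP7. CREBBP, the paralogue of p300, and SIRT1 rose by 0.63 and 0.56 on the log2 scale. The list was not called (camera adjusted p = 0.775). Of 47 readers and methylation enzymes, 23 were higher, 12 lower and 12 did not pass (23 and 12 adjusted over the list alone), with SETD1B at 0.55, KDM1A at -0.38 and DNMT3B at -0.71 (camera adjusted p = 0.109).

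**Figure D3:**
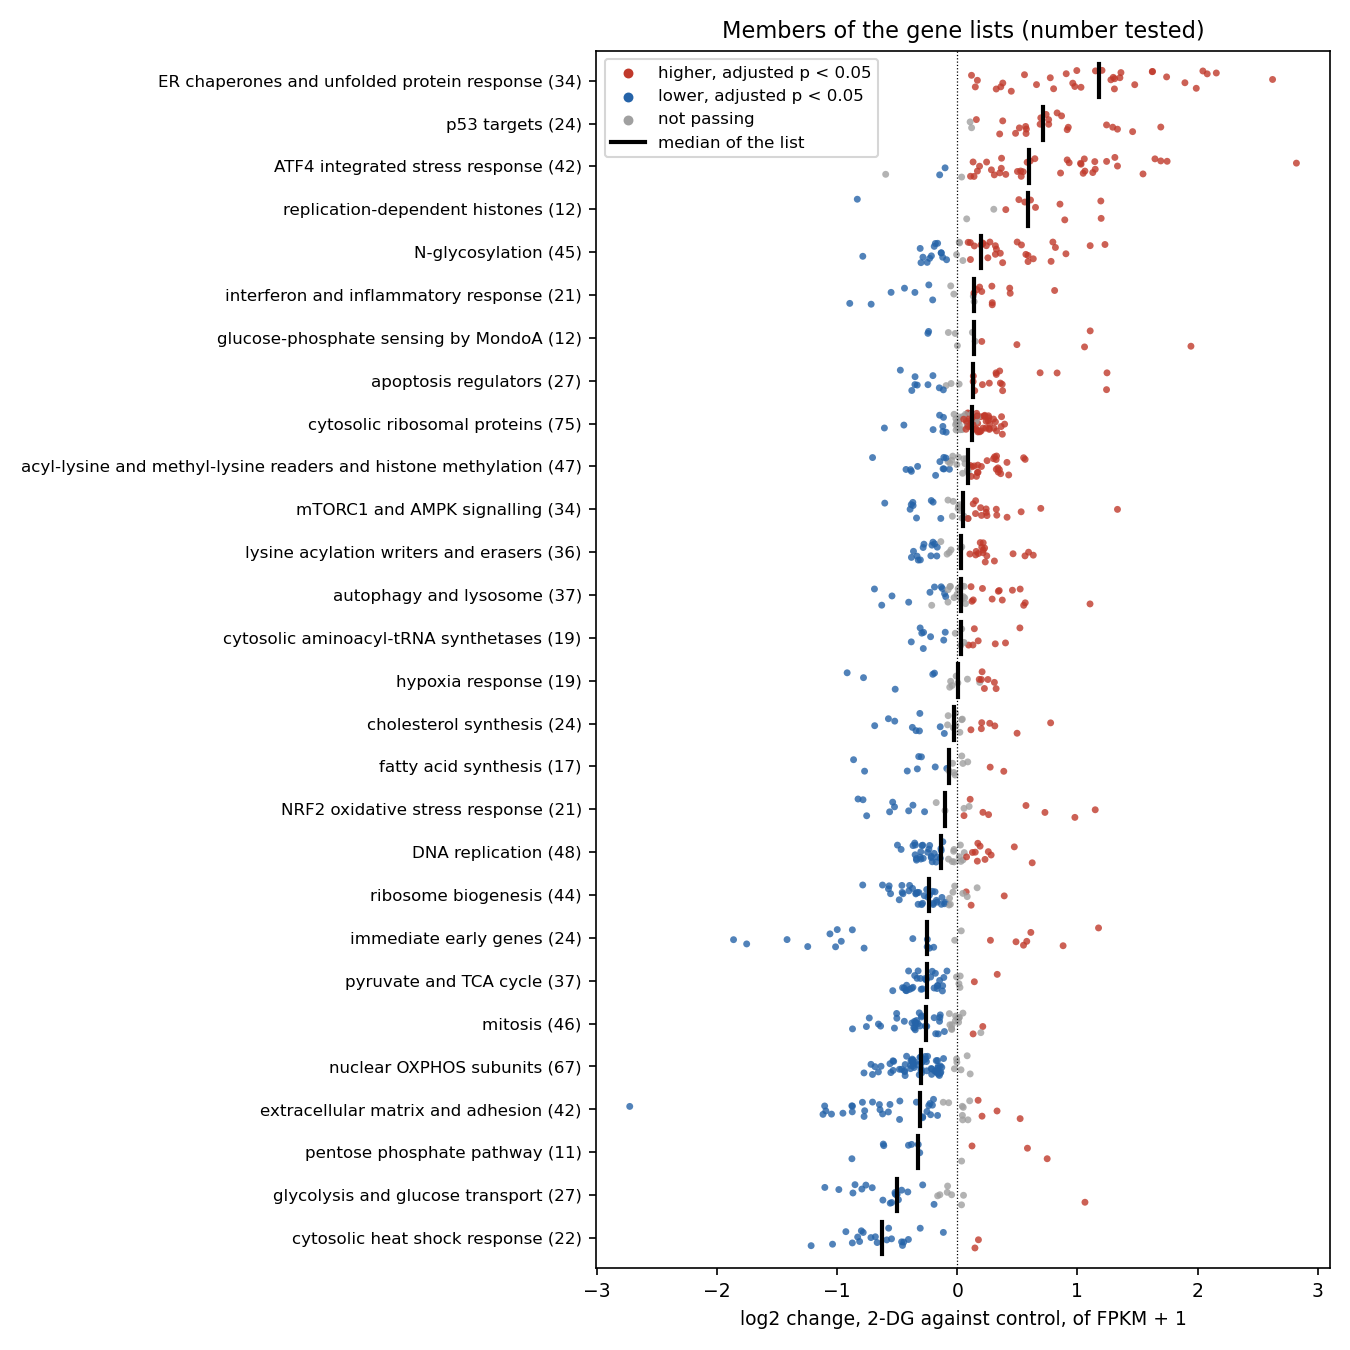
Log2 change in 2-DG against control, of FPKM + 1, for each tested member of the 28 gene lists with 5 or more tested genes, ordered by the list's median (black bar); red and blue points passed an adjusted p of 0.05, grey points did not. The ER chaperone list has the highest median, 1.18, and the cytosolic heat shock list the lowest, -0.63.

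Lipid synthesis genes went both ways. Of 24 cholesterol synthesis genes, 7 were higher, 9 lower and 8 did not pass (7 and 9 adjusted over the list alone), and FDPS and INSIG1 fell by 0.52 and 0.57 on the log2 scale (camera adjusted p = 0.514 for the list). Of 17 fatty acid synthesis genes, 2, the desaturases FADS1 and FADS2, were higher, 8 lower and 7 did not pass (2 and 8 adjusted over the list alone), and ELOVL6, SLC25A1 and FASN fell by 0.86, 0.77 and 0.42 (camera adjusted p = 0.167). Hypoxia genes were higher in 7 of 19 cases, lower in 5, and 7 did not pass (7 and 5 adjusted over the list alone), with EGLN3, CA12 and FAM162A at -0.92, -0.78 and -0.52. The hypoxia list had a mean of -0.04 against a median near 0 and a camera direction up (adjusted p = 0.765).

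Oxidative stress genes under NRF2 were higher in 8 of 21 cases, lower in 9, and 4 did not pass (9 and 9 adjusted over the list alone). HMOX1, heme oxygenase, and SLC7A11, the cystine transporter, rose 2.00-fold and 2.43-fold, and PRDX1, a peroxiredoxin, fell by 0.75 on the log2 scale (camera adjusted p = 0.765). Of 21 interferon and inflammatory genes, 10 were higher, 7 lower and 4 did not pass (10 and 7 adjusted over the list alone), with NFKBIA at 0.81, IFIT1 at -0.72 and DDX58 at -0.90 (camera adjusted p = 0.666). Of 37 autophagy and lysosome genes, 13 were higher, 10 lower and 14 did not pass (13 and 9 adjusted over the list alone), with WIPI1 at 1.10, OPTN at 0.57 and GABARAPL1 at -0.69 (camera adjusted p = 0.487). Of 34 mTORC1 and AMPK signalling genes, 15 were higher, 9 lower and 10 did not pass (15 and 9 adjusted over the list alone), with the sestrins SESN2 and SESN1 at 1.33 and 0.70 and TSC1 at 0.53 (camera adjusted p = 0.337).

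Genes often used as references also changed, with ACTB at 1122 ± 17.1 FPKM in control and 633 ± 11.9 in 2-DG (log2 change -0.83) and GAPDH at 1643 ± 49.3 and 1345 ± 10.7 FPKM (-0.29, and -0.14 after the length and GC trends were removed). Of 25 markers of other cell types, 5 were in the table, and those named here were below 3 FPKM in both groups. COL3A1 had a log2 change of -0.33 and SFN of -0.83.

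In all, 14 of 28 lists passed an adjusted p of 0.05 with the preset correlation, 6 up and 8 down. With an estimated correlation 0 passed, where 8 of the 28 had an unadjusted p under 0.05, and by fry, which asks only whether a list's genes move one way, 24 passed. The 50 highest genes took 19.6% ± 0.200 of the summed FPKM in control and 21.8% ± 0.136 in 2-DG (two-sided exact permutation test, p = 0.0286, the smallest that 4 against 4 libraries can give). Of the 9183 genes changed here, 9011 (98.1%) also had an adjusted p under 0.05 in the authors' deposited table, all 9011 in the same direction. The authors' deposited table lists 10044 of 14108 genes under that threshold, 5016 higher and 5028 lower, and 930 of them changed at least 2-fold. Of the 10044, 9266 were among the genes tested here. The authors' fold changes lie within 0.102 of the log2 ratio of mean FPKM, without a pseudocount of 1. The 930 and the 285 found here are therefore on unlike scales. Both analyses used the same 8 libraries, so their overlap is not independent evidence. The authors' fold changes and those computed here had a Pearson correlation of 0.974 across genes, which are not independent replicates.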

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

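No test in this part was chosen after the result was seen. In 13 of 216 groups of 4 libraries, 1 library lay far from the other 3 for its group's range, where chance gives about 1 in 20 groups, or 10.8 here. Control replicate 2 was the library apart in 8 of the 13. It was the highest for FOXCUT (9.61 FPKM, next 9.28), HK2 (16.7, next 16.2), MDH1 (126, next 119), PKM (694, next 683), PRDX1 (536, next 496) and SESN1 (7.89, next 7.44), and the lowest for EGLN3 (3.98, next 4.73). It also had the fewest reads of the controls (15048004, next 16459464). Its median gene differed from the other controls by 1.93 to 2.52 times counting noise, against 1.17 to 1.36 times among those 3, and without it 8954 genes changed, 270 of them at least 2-fold.

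The other 5 stood in different libraries. Control replicate 1 was highest for TNFRSF10B (31.3 FPKM, next 29.1) and control replicate 3 lowest for SFN (1.66, next 2.32). 2-DG replicate 1 was highest for HYOU1 (345, next 333) and PDIA4 (876, next 841), and 2-DG replicate 2 was lowest for MCM5 (70.3, next 74.4). In each of these genes the control and 2-DG libraries still did not overlap, which the rule required of HYOU1 and PDIA4.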

How the results depend on the processing

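Tests chosen after the data were seen were voom on recovered reads, removal of length and GC trends, and leaving out genes counted over too great a length. Across all alternatives the changed genes numbered from 6894 (filter of 5 FPKM, with fewer genes tested) to 9890 (no filter), against 9183. Leaving out 1 library gave 8572 to 8954 changed genes, 263 to 278 at least 2-fold and 13 or 14 lists. The 2-fold count of 285 became 622 with a pseudocount of 0.1, 686 with 0.01 and 679 by voom, where less or no shrinkage of low genes enters the fold, and stayed between 218 and 295 elsewhere. The 14 lists became 0 with an estimated correlation and 24 by fry, which tests another null. The tRNA synthetase list, not called, turned direction without control replicate 1 (adjusted p = 0.921) or 4 (0.987) and after trend removal (0.983), over a range of 0.794 to 0.987 without 1 library. The NRF2 list, not called, turned with the filter of 5 FPKM (0.901), and the cause was not tested for either. Of the genes named, none changed sign, and HK2 gained a call under 5 alternatives and SLC2A1 under 7, the replicate block among them. The replicate numbers did not pair the libraries (correlations of deviations -0.20, 0.17, 0.03 and 0.09, with 2 of 4 numbers best matched to their own), and a replicate block gave 9138 changed genes, 283 at least 2-fold and 14 lists. The top 50 share difference of 2.25 points was 1.74 for 20 genes and 2.10 for 100, and 2.18 to 2.31 without 1 library. At a threshold of 0.01, 98.5% of calls were also the authors'. Depth of 15048004 to 16726189 reads may limit genes near 1 FPKM, which was not tested by expression level.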

Other observations

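Tests chosen only after the result was seen were library scaling, few reads and lower ERK output; the lists for ERK targets, short-lived mRNAs and secretory machinery were also written after the largest changes were known. Genes for entry into the ER and for transport between ER and Golgi moved with the ER chaperones in 41 of 54 cases, 5 fell and 8 did not pass (limma, Benjamini-Hochberg). The translocon subunit SEC61A1 rose from 102 ± 2.49 to 243 ± 1.78 FPKM (SD, n = 4), the translocating chain protein TRAM1 from 43.2 ± 1.99 to 98.1 ± 4.05 FPKM and the cargo receptor TMED7 from 13.4 ± 0.965 to 25.6 ± 1.23 FPKM. The 5 members that fell were COPZ1, TMED3, SRP9, SRP14 and SPCS1, at -0.35, -0.33, -0.30, -0.21 and -0.19 on the log2 scale. The hypothesis that this machinery rises as a whole was given a bound of 0.3 for the list's median, and the median was 0.29 (95% bootstrap interval 0.21 to 0.51, camera p = 8.47e-09, p = 0.120 with an estimated correlation), so it stays open.

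The ER chaperone list took 0.753% ± 0.0201 of the summed FPKM in control and 2.14% ± 0.0380 in 2-DG (SD, n = 4; two-sided exact permutation p = 0.0286, the smallest possible, for each of 3 lists). The ribosomal protein list went from 18.3% ± 0.214 to 20.5% ± 0.217, and the glycolysis list fell from 1.45% ± 0.0121 to 1.04% ± 0.0178. Camera with the preset correlation had already called these 3 lists in the same libraries. The permutation p therefore adds no independent evidence, and the shares stand as sizes only.

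ETV4, ETV5, DUSP6 and EGR1, among the 10 largest falls, are known targets of ERK signalling, and 17 of 18 listed ERK targets fell, with SPRED3 the exception. Lower ERK output is a candidate explanation: the 14 targets outside the largest changes, CCND1, SPRY2 and DUSP5 among them, had a median log2 change of -0.69 (95% bootstrap interval -1.01 to -0.33, camera p = 1.44e-05, p = 0.0379 with an estimated correlation). A general fall of short-lived mRNAs was argued against. The 28 such mRNAs outside the list had a median of 0.0417 (interval -0.14 to 0.16) against -0.94 for all 18 targets. They went both ways, with 11 higher, 9 lower and 8 not passing, KLF11 at 1.11 and IER2 at -0.78 among them. Members that are induced could offset a loss of others, so mRNA loss itself was not tested. ERK activity itself was not measured, so this remains a hypothesis found and tested on the same libraries.

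The real grouping gave 9183 changed genes and 285 changed at least 2-fold, and each of the other 34 of 35 splits of the 8 libraries gave 0, so 1 of 35 splits, the fewest possible, was as large in both counts. The other splits mix the treatment groups, so the difference between the groups enters their spread and lowers their counts. The counts therefore argue against a random assignment of these 8 libraries only at 1 of 35. They do not exclude a chance difference between the cultures that the libraries came from. For the number of lists neither can be excluded, since 2 of the 35 splits, the real one included, gave 14. Splits that hold the treatments in unequal numbers keep part of the treatment difference, so this count does not measure chance alone. A wrong scale for the libraries would move the 285 genes one way, but 53.3% were higher and 95.1% of the 285 kept both thresholds after quantile normalization. A trend on gene length or GC content was present (Spearman's rho of the change 0.18 and -0.18 across genes). Of the 285, 79.6% kept both thresholds after its removal, so it cannot be the whole cause. After removal 277 genes passed both thresholds, 227 of them from the 285, and 67.5% of the 277 were higher.

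In 49 genes, replicates of at least 1 group differed at least 4-fold, with the highest at 1 FPKM or more. HRAS, PRPF8 and AATF did so in both groups. Few reads were argued against as a cause, since the median of the highest read count over the 49 genes was 378. Counting over more than 1 copy of a sequence, such as alternate haplotypes in the reference, is a candidate explanation: 46.9% of the 49 had a counted length at least 1.8 times the reference, against 2.67% of 13692 other genes (Fisher's exact test, p = 3.87e-23). Where the authors' reads were placed was not tested. The remaining genes, PRPF8 (1.74 times the reference) and AATF (1.23 times) among them, stay open. None of the 49 was named in the report by its rule.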
